A study of Mus musculus with 4 samples.

How the data were processed

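The study sorted cells carrying a leptin receptor reporter (Lepr-cre driving tdTomato) from the hypothalamus of C57BL/6 mice into 384-well plates. Per the labels, 3 plates came from fed mice and 1 plate from mice fasted for 24 h. The reporter marks cells in which the Lepr promoter was active at any time, so a marked cell need not hold Lepr transcripts when sorted. How many animals gave each plate, their sex and the time of day of collection are not given in the sources used here. Because nothing says that the plates came from separate animals, the p-values measure only the spread between these plates.

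Libraries were made with CEL-seq2, with a UMI of 6 bases, a barcode per well and ERCC spike-ins, and per the labels reads were trimmed with Trim Galore and aligned with STAR to mm10. The deposited values are expected counts, that is UMIs per gene and well corrected for UMI collisions, with no normalization and no filter on wells. Every value traced back to a whole number of UMIs out of 4096 possible ones within a tolerance of 1e-06. The correction added 0.784, 1.38 and 1.19% to the totals of fed plates 1, 2 and 3 and 2.04% to that of the fasted plate. The highest count of 1 gene in 1 well was 3615 UMIs, on the fasted plate. The UMI counter and the annotation release are not given in the sources used here. Of 35998 gene identifiers in the tables, 35945 are in GENCODE vM21, from which coordinates on GRCm38 (mm10) were taken.

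Wells were kept with at least 1000 transcripts outside spike-ins and mitochondrial genes and a mitochondrial share under 30%. This kept 356, 322 and 331 wells of the fed plates and 270 of the fasted plate, 1279 of 1536 in all. Their median transcripts per cell were 13507, 7750, 8356 and 9708.5, and the plate totals ran from 4398233 to 5529965 transcripts. Median mitochondrial shares were 6.51, 5.76 and 6.41% on the fed plates and 8.34% on the fasted plate. No doublet caller was used in the reported values, since 1 cell was sorted per well. Scrublet called 1, 1 and 3 doublets on the fed plates and 3 on the fasted plate, and leaving them out is an alternative.

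Cells were clustered with scanpy 1.11.5 (Python 3.11.15, anndata 0.12.19, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3) on 2000 variable genes, 30 principal components and 10 neighbours, with Leiden resolution 1.5. The features left out Agrp, Npy, Pomc, Cartpt and the lists of transcription factors, receptors, fasting and stress genes. This gave 27 clusters. Clusters were named from 29 fixed marker sets when at least 3 markers of a set were enriched by a log2 fold of at least 1 and seen in at least 25% of cells. The share of markers met also had to exceed that of every other set. Among the 10 top genes of the cluster, no other set could have more markers than the chosen set. Clusters that failed these rules stayed unnamed. A cluster counted as neuronal at 40 or more transcripts of 9 neuron markers per 10000, a threshold set after the data were seen. The pars tuberalis-like cluster, at 46.1, was kept outside neurons. Neurons outside the AgRP clusters were clustered again on 1500 genes, 25 components and 8 neighbours into 14 clusters. Names with "-like" rest on these markers alone.

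Counts were rounded to whole numbers, summed per plate over the cells named, and compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1), using filterByExpr, TMM factors, robust dispersion estimates and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Mitochondrial genes and spike-ins stayed out of the sums. With 3 fed plates and 1 fasted plate the fit has 2 residual degrees of freedom, takes its spread from the fed plates and assumes that the fasted plate varies alike. Plate and feeding state cannot be told apart in this design. Besides all kept cells, all neurons, AgRP-like neurons and the remaining neurons, 4 classes had at least 10 cells on the fasted plate and on at least 2 fed plates, which makes 8 comparisons. Each class was also compared with the remaining cells of the same plates, or with the remaining neurons, with plate as block, where at least 3 plates held 5 or more cells. Levels are CPM after TMM scaling, given as mean ± SD over fed plates, and folds are on the log2 scale, fasted minus fed, with their standard error (SE). Lepr levels by class or cluster are CPM of plain totals. The same holds for levels of Chga, Cga, Bpifa1 and Vgf that the text gives without a fold, and for Npy in wells under 1000 transcripts. Such levels differ somewhat from those after TMM scaling. Shares carry exact Clopper-Pearson intervals at 95%. Intervals of shares, levels and ratios of counts, and floors, cover counting error only. Where genes called in 1 contrast are set against another, the interval at 95% is of a median over genes taken as independent. In the endothelial-like tests the range for RNA spread runs from the lowest to the highest of 10 genes. The interval for Y-only cells joins 2000 resamplings of cells with a Poisson interval. None covers the spread between plates. A fold against a library at 0 was bounded with 3 counts per library.

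Gene lists (23 in all) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison, where at least 3 members were tested. With an estimated correlation camera tests on the residual degrees of freedom of the fit, here 2 at most. Few lists can pass under that setting, so a list that failed it is neither shown nor ruled out. No list called with the preset correlation was called with an estimated correlation in any of the 8 comparisons. By fry, heat shock genes in neurons other than AgRP-like were the only list called, at adjusted p = 0.0187. The melanocortin peptides had too few tested members and the mitochondrial genome genes were left out of the sums, so neither list was tested. Sex of cells was read from Xist and Y-linked transcripts.

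The lists, marker sets, tests and thresholds were chosen before the data were examined, except where stated. Genes were named by a fixed rule: Agrp, Npy, Pomc, Cartpt, Lepr and Socs3, then the 10 highest and 10 lowest folds among genes past the threshold with a mean of at least 20 CPM. Where fewer passed in a direction, genes of smallest p were added until 5 were named, stated as not passing. Up to 4 members per called list were named by smallest p, and for each class up to 6 transcription factors and 6 receptors and Lepr. Some genes that this rule names are not reported here. Bpifa1, Cga and the genes of single clusters were named after their values were seen, except where this rule names them.

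Simulated counts had the same design and 1 common dispersion for all genes, estimated from the fed plates, so the spread of single genes was not simulated. Among genes with a summed count of at least 40, 100 were changed by 1 log2 unit and 100 by 2. The test recovered 34 and 87 of them in AgRP-like neurons, 15 and 77 in the remaining neurons, 27 and 82 in all neurons, and 1 and 23 in all kept cells. Recovery was 20 and 75 in tanycyte-like, 23 and 69 in astrocyte-like, 0 and 4 in endothelial-like, and 3 and 33 in vascular and leptomeningeal cell-like sums. For classes against the remaining cells, with an assumed dispersion of 0.1, it ran at 2 log2 units from 5 of 100 in pericytes to 79 of 100 in AgRP-like neurons. For differences of folds, with an assumed dispersion shared by all genes, it was 4 and 45 against the remaining neurons and 3 and 38 against tanycyte-like cells.

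Alternatives fixed in advance were DESeq2's size factors, the Wald test of DESeq2 1.42.0, no filter on low counts, leaving out each fed plate, minimum transcripts of 500 and 2000, no mitochondrial limit, lower and higher clustering resolutions (0.67 and 1.5 times), all variable genes as features, thinning of each cell to 1000 transcripts, an estimated correlation for lists, and no plate block. The fit on Xist-only cells and the sums without Scrublet doublets were chosen after the data were seen, as were the tests of differences between folds. Figures were drawn with matplotlib 3.10.9. The barcode list among the files holds no measurement and was not used here.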

Results

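The cells caught by the leptin receptor reporter fell into neurons, tanycyte-like cells that line the floor of the ventricle, and glial and vascular cells. Neurons made up 34.3, 34.5 and 30.8% of kept cells on fed plates 1, 2 and 3 and 17.8% on the fasted plate (95% interval 13.4 to 22.9). AgRP-like neurons, the arcuate neurons that make Agrp and Npy and drive feeding, held 23.0, 18.3 and 8.16% on the fed plates and 8.52% on the fasted plate. They came from different clusters on different plates. Cluster 3 held 79 of the 82 AgRP-like cells of fed plate 1, cluster 4 held 51 of 59 and 25 of 27 on fed plates 2 and 3, and cluster 21 held 22 of 23 on the fasted plate. Cluster 21 was led by Vgf, Agrp, Acvr1c, Ghr, Corin and Lepr.

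Oligodendrocyte-like cells held 13.0% of the fasted plate (9.20 to 17.6) and 0.562, 2.48 and 1.81% of the fed plates. Microglia or macrophage-like cells held 5.93% of the fasted plate (3.42 to 9.45), 1.24 and 1.51% of fed plates 2 and 3, and 0 of 356 cells on fed plate 1, which allows up to 1.03%. Astrocyte-like cells held 16.3% of the fasted plate and 0.843, 8.70 and 11.2% of the fed plates. Vascular and leptomeningeal cell-like (VLMC-like) cells, the fibroblasts of the meninges and vessel walls, held 4.81% of the fasted plate and 7.58, 9.32 and 9.37% of the fed plates. Tanycyte-like cells, at 15.9%, lay within the fed range of 14.3 to 23.0%. Endothelial-like cells held 19.4% of fed plate 1 (8.43% at higher clustering resolution), against 5.90 and 5.74% on the other fed plates and 6.30% on the fasted plate. Of the 69 on fed plate 1, 55 formed cluster 8, which no other plate entered. It was led by Lcn2, Ackr1, Lrg1, Ch25h, Cxcl1, Slc38a5, Ptgs2, Cfb, Gm20547 and Vwf, with inflammation and acute-phase genes such as Lcn2, Cxcl1 and Ptgs2 among them. Pars tuberalis-like cells, from the pituitary stalk, held 5.90% of fed plate 1 and 7.41% of the fasted plate, against 0 and 0.302% of fed plates 2 and 3. POMC-like neurons were 3, 3 and 2 cells on the fed plates and 0 of 270 on the fasted plate, which allows up to 1.36%. The unnamed neuron cluster N3 was also led by Pomc, with 3, 2 and 6 cells on the fed plates and 5 on the fasted plate. The 0 therefore does not mean that neurons with Pomc were absent there. Unnamed clusters held 23.0, 18.3, 23.6 and 13.0%. Among them were cluster 16, tied between the pericyte and endothelial sets, and clusters 18 and 19, with 6 of 6 endothelial markers. Clusters 16, 18 and 19 held 19, 14 and 18 cells of fed plate 1 and 2, 6 and 2 of the fasted plate. On fed plate 2 they held 3, 3 and 2 cells and on fed plate 3 they held 4, 3 and 4. These cells enter no endothelial-like or pericyte-like share or sum. Cluster 14, just under the neuron threshold, held 1.12, 6.21, 0.906 and 1.11%. The sort and the count of wells that passed (270 on the fasted plate) set which cells enter, and 3 plates against 1 cannot go below p = 0.25 in a one-sided exact permutation test, so the shares were described and not tested.

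**Figure D1:**
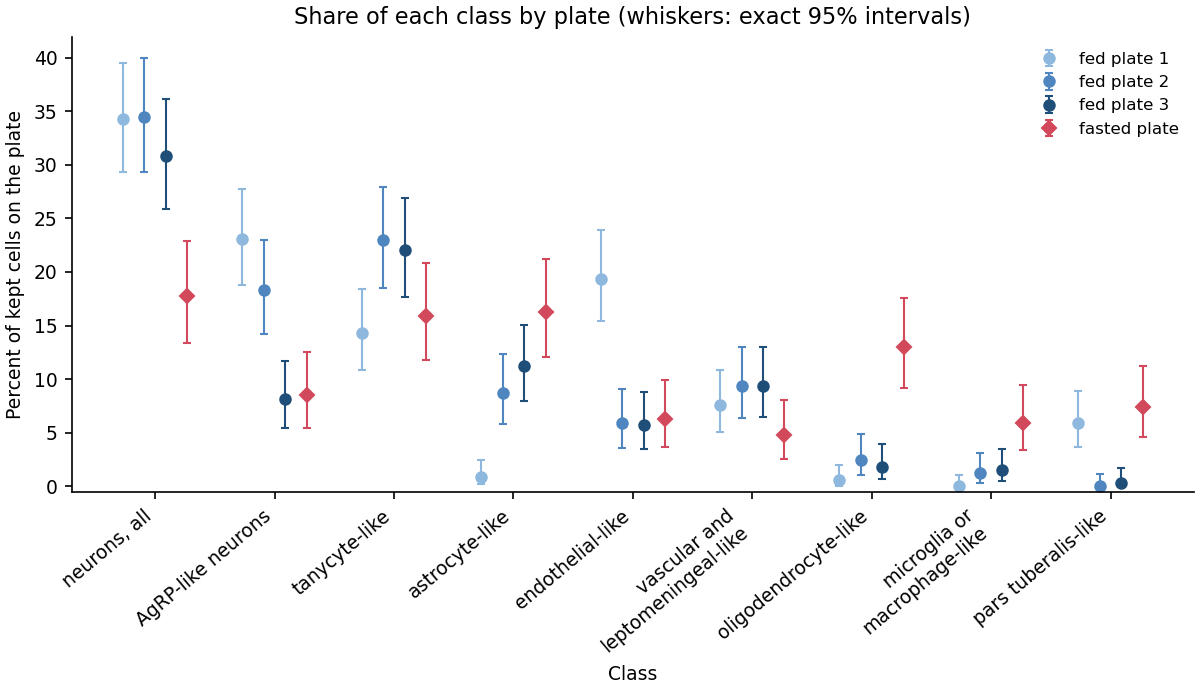
Share of kept cells (%, vertical axis) in each class (horizontal axis) on fed plates 1, 2 and 3 and on the fasted plate, with exact 95% intervals as whiskers. Oligodendrocyte-like cells hold 13.0% of the fasted plate and at most 2.48% of a fed plate.

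The plates differed in the sex of their cells. Cells with Xist and no Y-linked transcript were 6.74, 51.6 and 42.0% of fed plates 1, 2 and 3 and 84.4% of the fasted plate, while cells with Y-linked transcripts and no Xist were 75.6, 25.2 and 29.6% and 0%. Within fed plates 2 and 3, Xist-only and Y-only cells differed in 14 of 7585 genes in AgRP-like neurons, 10 of them outside the sex-linked genes (edgeR). Outside these genes they differed in 152 of 13419 in all kept cells, 16 of 10987 in all neurons, 9 of 9439 in other neurons, 0 of 5695 in tanycyte-like (4 with the sex-linked genes) and 34 of 1622 in VLMC-like cells.

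Lepr itself was unevenly spread over the marked cells. After thinning each cell to 1000 transcripts, Lepr was seen in 11.9% of VLMC-like cells (12 of 101, 6.29 to 19.8), 7.29% of neurons other than AgRP-like (4.04 to 11.9) and 5.24% of AgRP-like neurons (2.54 to 9.42). It was seen in 4.03% of endothelial-like cells (1.32 to 9.16), in 0.415% of tanycyte-like cells, and in 0 of 112 astrocyte-like cells, which allows detection in up to 3.24% at that depth. Unthinned, the shares were 45.5, 46.4, 54.5, 18.5, 4.15 and 3.57% in the same order, at median depths of 5406, 26551.5, 30494, 9047.5, 6893 and 4798.5 transcripts. Oligodendrocyte-like cells, taken here as background, had Lepr in 0 of 51 cells after thinning (up to 6.98% at that depth) and 3.92% unthinned at a median of 9016 transcripts. On the fed plates Lepr stood at 171 ± 57.7 CPM in VLMC-like cells, 44.2 ± 23.9 in neurons other than AgRP-like, 36.3 ± 9.45 in AgRP-like neurons, 28.5 ± 7.17 in endothelial-like and 3.98 ± 1.18 in tanycyte-like cells (SD, n = 3 plates). Against the remaining cells of the same plates, Lepr was higher in VLMC-like cells by 2.32 on the log2 scale (SE 0.29, adjusted p = 1.8e-14). It was lower in tanycyte-like (-3.37), astrocyte-like, oligodendrocyte-like and oligodendrocyte precursor-like cells. The last 3 held 4, 2 and 1 Lepr counts in all, with 0 on at least 1 plate each, so no fold is given for them. Differences of 0.40 in AgRP-like neurons against other neurons (adjusted p = 0.610), -0.56 in endothelial-like (0.264) and -0.09 in pericyte-like cells (0.967) did not pass. The first stood at -0.20 without the fasted plate and 0.75 without fed plate 3, and the last at 0.46 without fed plate 3. Without the fasted plate the call in oligodendrocyte-like cells was lost (adjusted p = 0.178).

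**Figure D2:**
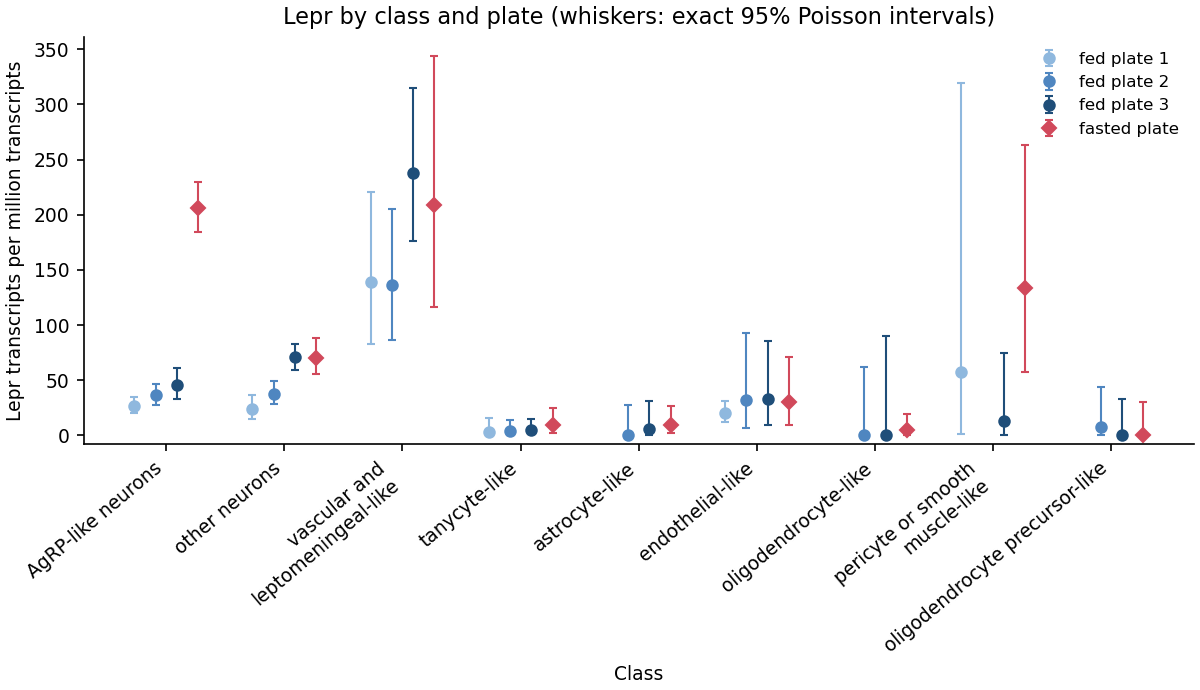
Lepr level (CPM, vertical axis) by class (horizontal axis), 1 point per plate with 5 or more cells, with exact Poisson intervals at 95%. AgRP-like neurons stand at 26.9, 36.3 and 45.8 CPM on the fed plates and 206 CPM on the fasted plate.

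AgRP-like neurons were set apart from other neurons by 20 of 84 tested transcription factors that were higher and 39 that were lower, and by 10 higher and 18 lower of 46 tested receptors. Cited1 (2.45, SE 0.23), Bsx (2.32, SE 0.22), a homeobox factor of the arcuate nucleus, and Six6 (2.00, SE 0.18) led the factors not used for naming, followed by Zfpm2 (1.89), Satb1 (1.74) and Mkx (1.40). The receptors for corticotropin-releasing hormone, Crhr1 (3.06, SE 0.43), for ghrelin, Ghsr (2.80, SE 0.33), for calcitonin, Calcr (2.53, SE 0.24), and for growth hormone, Ghr (2.43, SE 0.10), were highest, then Npy2r (2.42) and Adra1a (2.19). Each of these passed the edgeR test over 4 plates, and Mkx did not without fed plate 3 (adjusted p = 0.128).

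Among tanycyte-like cells 35 of 105 tested transcription factors and 5 of 48 receptors were higher than in the remaining cells, led by Fezf2 (5.49, SE 0.50), Nkx2-4 (3.90, SE 0.23), Nfix (3.18), Nkx2-1 (3.12), Tbx2 (3.04) and, among receptors, Ntrk2 (3.00, SE 0.15) and Bmpr1b (2.03). VLMC-like cells had 31 of 108 factors and 11 of 52 receptors higher, among them Tbx18 (6.76, SE 0.30), Foxd1 (5.81), Zic4 (5.71), Zic1 (5.32), Ptgfr, the receptor for prostaglandin F, at 5.22 (SE 0.62), Adra2a (3.00) and Npr3 (2.93, adjusted p = 0.396 without fed plate 3). Astrocyte-like cells had 43 of 110 factors and 11 of 46 receptors higher, with Foxb1 (5.17), Rfx4 (5.10), Nkx6-2 (4.50), Bmpr1b (4.81) and Ramp1 (3.74). Endothelial-like cells had 21 of 107 and 5 of 49, with Lef1 (5.64), Zic2 (3.68), Ebf1 (3.29), Calcrl (3.67) and Igf1r (3.53), and Lef1 did not pass without fed plate 2 (0.0709) or the fasted plate (0.0609). Oligodendrocyte precursor-like cells had 30 of 111 and 9 of 51, with Pou3f1 (4.69), Npas1 (4.43) and Calcrl (3.46). Oligodendrocyte-like cells had 12 of 106 and 1 of 48, Adora1 (2.98), and the 13 became 6 without the fasted plate, which holds 35 of their 51 cells. Pericyte-like cells had 18 of 105 and 2 of 46, with Tbx2 (4.77) and Npy1r (2.86), and the 20 became 10 without fed plate 3, where Npy1r did not pass (0.235), and 9 without the fasted plate.

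In AgRP-like neurons of the fasted plate, Agrp (ENSMUSG00000005705, chromosome 8, 105566698 to 105637393) stood at 2603 CPM against 1316 ± 163 CPM on the fed plates (SD, n = 3), a log2 difference of 0.98 (SE 0.22, adjusted p = 0.0063 by edgeR's quasi-likelihood test). Vgf, a precursor of secreted neuropeptides (ENSMUSG00000037428, chromosome 5, 137026392 to 137033351), rose from 93.5 ± 14.9 to 1395 CPM (3.88, SE 0.20, adjusted p = 1.2e-15). Lepr (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352) rose from 36.5 ± 9.18 to 212 CPM (2.58, SE 0.23, adjusted p = 1.4e-09). The heat shock gene Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238) fell from 208 ± 22.5 to 10.1 CPM (-4.35, SE 0.33, adjusted p = 4.6e-11), and Dbp, a clock-controlled transcription factor (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), from 81.3 ± 28.8 to 6.34 CPM (-3.70, SE 0.49, adjusted p = 2.5e-04). Npy (ENSMUSG00000029819, chromosome 6, 49822710 to 49829507) stood at 10502 CPM against 6995 ± 1130 CPM, a difference of 0.59 that did not pass (SE 0.26, adjusted p = 0.212). Pomc (0.11, adjusted p = 0.923), Cartpt (-0.38, 0.842) and the leptin feedback gene Socs3 (-0.73, 0.262) did not pass either.

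Of 13075 genes tested in AgRP-like neurons, 405 were higher and 249 lower in the fasted plate. Besides Vgf and Lepr, the largest increases were in Nptx2, a secreted synaptic pentraxin, from 9.79 ± 7.66 to 120 CPM (3.48, SE 0.44), the adhesion receptor Adgrg2 (3.31, SE 0.41), Cd24a (2.52, SE 0.27) and Lxn (2.51, SE 0.26), and in the processed pseudogenes Gm6433 (4.39), Gm6290 (2.76), Rpl10-ps2 (2.48) and Gm9403 (2.45). Counts of pseudogenes are uncertain because reads of their parent genes can align to them, and 47 of 434 tested pseudogenes were called, 43 of them higher. The largest decreases after Hspa1b and Dbp were in the cholesterol enzyme Nsdhl from 35.6 to 5.70 CPM (-2.64, SE 0.47), Gas2 from 25.7 to 4.43 CPM (-2.51, SE 0.51), the clock gene Per3 from 136 to 28.5 CPM (-2.24, SE 0.27), Lmo3 (-2.15, SE 0.35), the pseudogene Gm14539 (-2.91) and the lincRNA Gm28928 (-2.12). Uty, on the Y chromosome, had a mean of 33.0 CPM on the fed plates and 0 counts on the fasted plate, at least 17.4-fold lower.

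**Figure D3:**
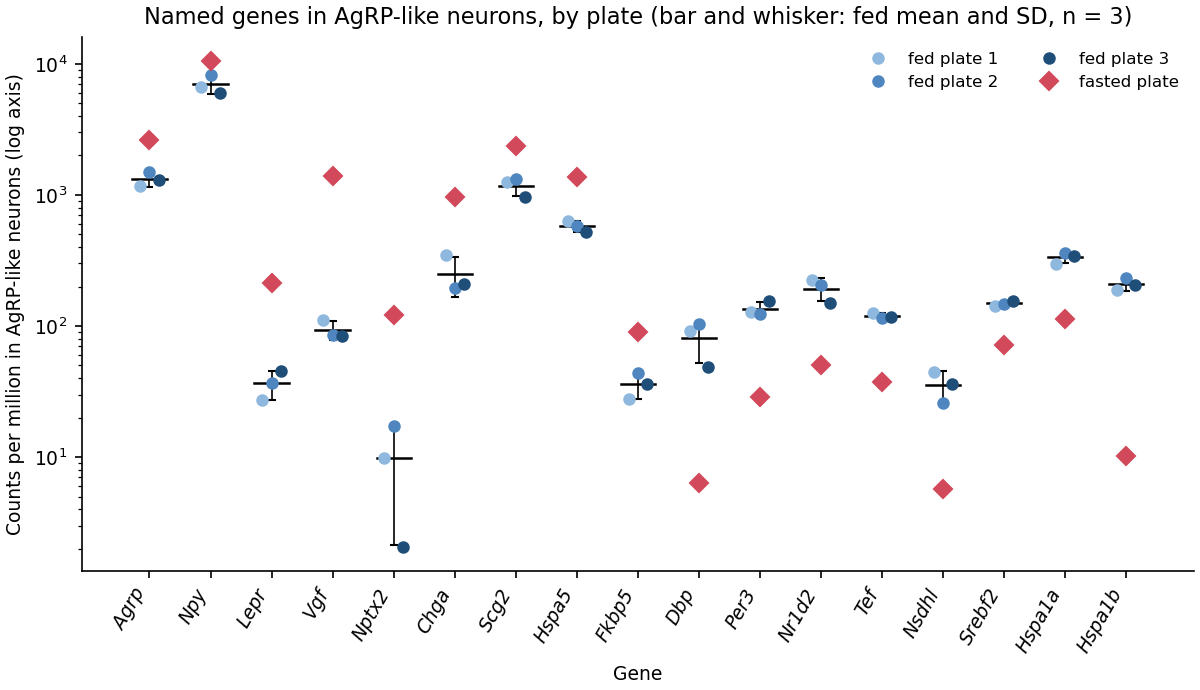
Level (CPM, logarithmic axis) of named genes in AgRP-like neurons, 1 point per plate (circles fed, diamonds fasted), with bars and whiskers for the fed mean and SD (n = 3). Vgf stands at 1395 CPM on the fasted plate against 84.1 to 111 CPM on the fed plates, and Hspa1b at 10.1 against 187 to 232 CPM.

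In AgRP-like neurons 10 of the fixed lists passed camera at the preset correlation, and none with an estimated correlation. Of 6 AgRP fasting peptides and secreted proteins 4 rose and 2 did not pass (5 adjusted over the list alone), with a median of 0.98. The risers were Agrp, Vgf, the granin Scg2 (1.01, SE 0.23) and Nucb2 (0.97, SE 0.26), and the list passed camera at adjusted p = 3.4e-16 (adjusted p = 0.178 with an estimated correlation). Of 14 genes of neuropeptide processing and dense core vesicles 6 rose and none fell (7 higher and 1 lower adjusted over the list alone), among them Chga (1.92, SE 0.26) and Chgb (0.84, SE 0.22). Their camera adjusted p was 3.7e-09 (adjusted p = 0.245 with an estimated correlation). Chga was at 35214 and 25907 CPM in pars tuberalis-like cells of fed plate 1 and the fasted plate, and Cga, the hormone subunit those cells make, was at 19.5, 0 and 3.12 CPM in AgRP-like neurons of the fed plates and 46.9 CPM on the fasted plate. On the fasted plate Chga stood at 933 CPM in AgRP-like and 1014 CPM in other neurons. It stood there at 1002, 869, 944 and 1613 CPM in tanycyte-like, astrocyte-like, endothelial-like and VLMC-like cells. Bpifa1, seen on the fasted plate alone, was at 1213 CPM in pars tuberalis-like cells and 16.7 CPM in AgRP-like neurons. The rise of Chga in AgRP-like neurons therefore cannot be told apart from RNA of other wells. Of 17 neuropeptides 2 rose, Agrp and Vgf, with a median of 0.50 (2 adjusted over the list alone, camera adjusted p = 5.3e-05, adjusted p = 0.263 with an estimated correlation). Nts (2.65, adjusted p = 0.188) and Nmb (-1.80, 0.139) did not pass.

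Of 17 genes of ER stress and the unfolded protein response 6 rose and none fell (7 adjusted over the list alone), with the chaperone Hspa5 going from 577 ± 53.9 to 1373 CPM (1.25, SE 0.21), Pdia6 (0.91), Dnajc3 (0.85) and Pdia3 (0.77). Camera gave adjusted p = 3.5e-05 (adjusted p = 0.263 with an estimated correlation). Of 10 glucocorticoid response genes 3 rose (4 adjusted over the list alone), with a median of 0.49: the cell cycle inhibitor Cdkn1a (4.81, SE 0.75, from 4 transcripts over the fed plates), Fkbp5 (1.34, SE 0.26) and the kinase gene Sgk1 (0.97, SE 0.24). Errfi1 was at 0.58 (adjusted p = 0.123), and the list passed camera at adjusted p = 0.0031 (adjusted p = 0.263 with an estimated correlation).

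Of 16 circadian clock genes 10 fell and none rose (10 lower and 3 higher adjusted over the list alone), with a median of -1.45. They included Dbp, Per3, Nr1d2 from 193 to 50.1 CPM (-1.96, SE 0.27) and Tef from 119 to 37.4 CPM (-1.67, SE 0.26), with camera adjusted p = 1.7e-11 (adjusted p = 0.178 with an estimated correlation). Of 17 cholesterol synthesis genes 7 fell and none rose (10 adjusted over the list alone), with a median of -0.89, among them Nsdhl, Msmo1 (-1.14, SE 0.25) and Srebf2, the master regulator of the pathway (-1.05, SE 0.23). Camera gave adjusted p = 7.3e-08 (adjusted p = 0.263 with an estimated correlation). Of 10 genes of heat shock and dissociation stress 5 fell and 1 rose, also adjusted over the list alone, among them Hspa1b, its near-identical paralog Hspa1a (-1.57, SE 0.24), Dnajb1 (-0.87) and Hsph1 (-0.85), with camera adjusted p = 4.6e-07 (adjusted p = 0.217 with an estimated correlation). Reads of Hspa1a and Hspa1b are hard to assign to either gene. Within fed plates 2 and 3, Xist-only cells were below Y-only cells in Hspa1a (-1.44, adjusted p = 5.6e-07) and Dnajb1 (-0.73, adjusted p = 0.016), with Hspa1b at -1.64 (adjusted p = 0.104). Of 17 genes of synaptic vesicle release 1 fell, Cplx2 (-1.25, SE 0.25), also adjusted over the list alone (camera adjusted p = 0.0132, adjusted p = 0.520 with an estimated correlation). None of 25 nuclear genes of oxidative phosphorylation passed, with a median of -0.28 and Ndufa2 at -0.65 (edgeR adjusted p = 0.0841, camera 0.0051, adjusted p = 0.520 with an estimated correlation).

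Other lists were not called in AgRP-like neurons. Leptin receptor signalling had 1 of 15 members higher, Lepr, and a median of 0.16 (camera adjusted p = 0.145). Immediate early genes had 1 higher and 1 lower of 14 (0.339), glycolysis and glucose transport 2 lower of 17 (0.108), glutamate receptors 2 higher of 15 (0.288), GABA synthesis, transport and receptors 2 higher and 1 lower of 15 (0.539), and ribosomal proteins 4 higher of 37 (0.125). Transcription factors had 3 higher and 3 lower of 77 (0.911) and receptors 7 higher and 3 lower of 53 (0.345). No member passed among 15 genes of fatty acid oxidation and ketogenesis (0.267), 16 of autophagy and lysosome (0.908) and 9 of the interferon response (0.2004). Adjusted over the list alone these counts were alike, except for 2 lower genes of fatty acid oxidation, 1 higher and 1 lower of autophagy, 2 higher and 2 lower of glycolysis, 2 higher and 2 lower of GABA, 3 higher and 4 lower transcription factors and 8 higher and 6 lower receptors.

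**Figure D4:**
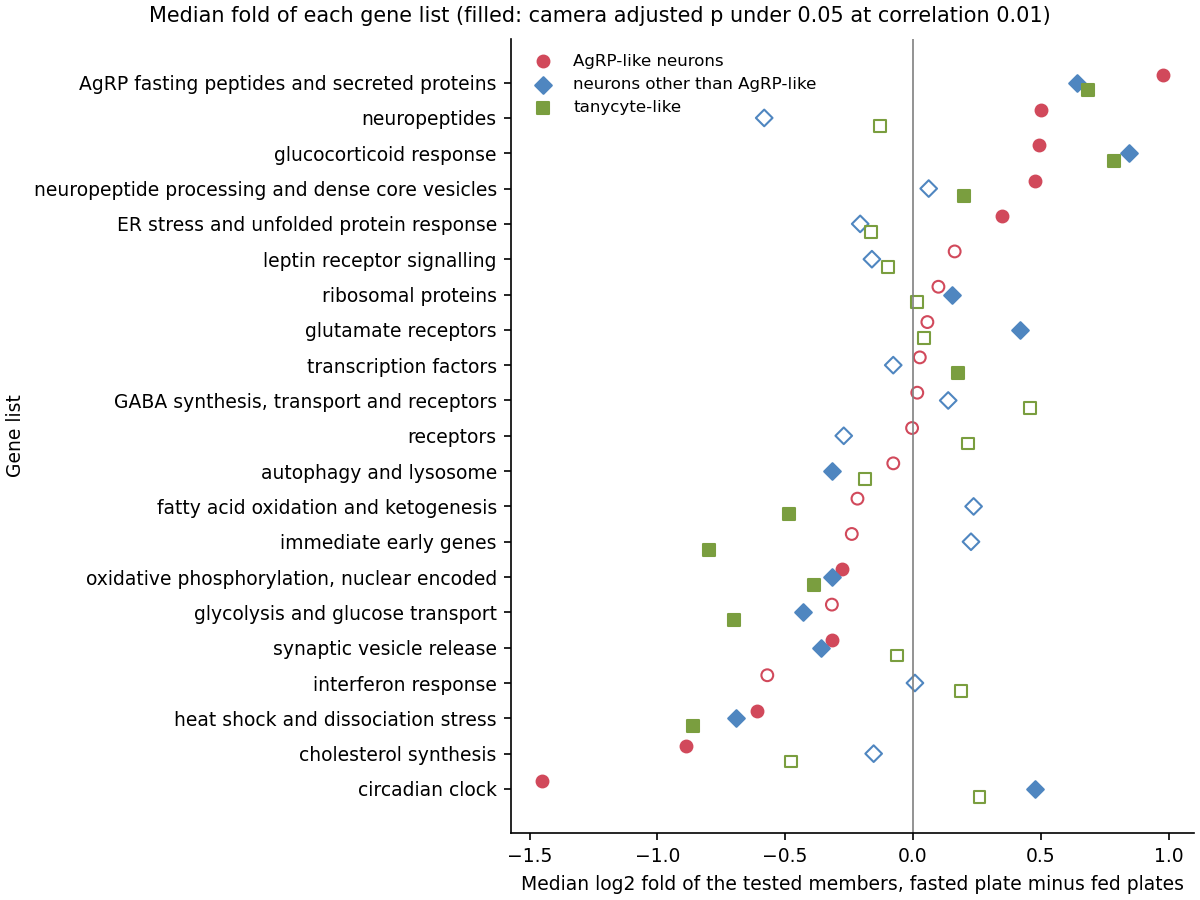
Median log2 difference, fasted minus fed (horizontal axis), of each fixed gene list (vertical axis) in AgRP-like neurons (circles), other neurons (diamonds) and tanycyte-like cells (squares), filled where camera called the list. In AgRP-like neurons the circadian clock list stands at -1.45 and the AgRP fasting peptides at 0.98.

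Each of these 654 calls rests on 1 fasted plate of 23 AgRP-like cells, with a median of 65352 transcripts per cell against 26017, 30397 and 33243 on the fed plates. The fasted plate against each pair of fed plates gave 932, 495 and 943 calls without fed plates 1, 2 and 3, while each fed plate against the other fed plates gave 187, 29 and 31. Without fed plate 2 the calls of Agrp (1.08, adjusted p = 0.0982), Scg2 (0.0821), Nucb2 (0.0688), Dnajb1 (0.270), Hsph1 (0.198), Pdia6 (0.0590), Dnajc3 (0.107), Pdia3 (0.0881), Sgk1 (0.114) and Chgb (0.260) were lost. With Xist-only cells of fed plates 2 and 3 and the fasted plate 56 genes were called, against 932 in all cells of these plates. Of the 654, 645 were tested there, and all 645 had the same direction, with a median fold 0.949 times that in all cells. Of the 23 AgRP-like cells of the fasted plate 22 were Xist-only, as were 41 of 59 on fed plate 2 and 6 of 27 on fed plate 3. The sums thus share cells with those that gave the calls, so the shared direction is no independent evidence.

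**Figure D5:**
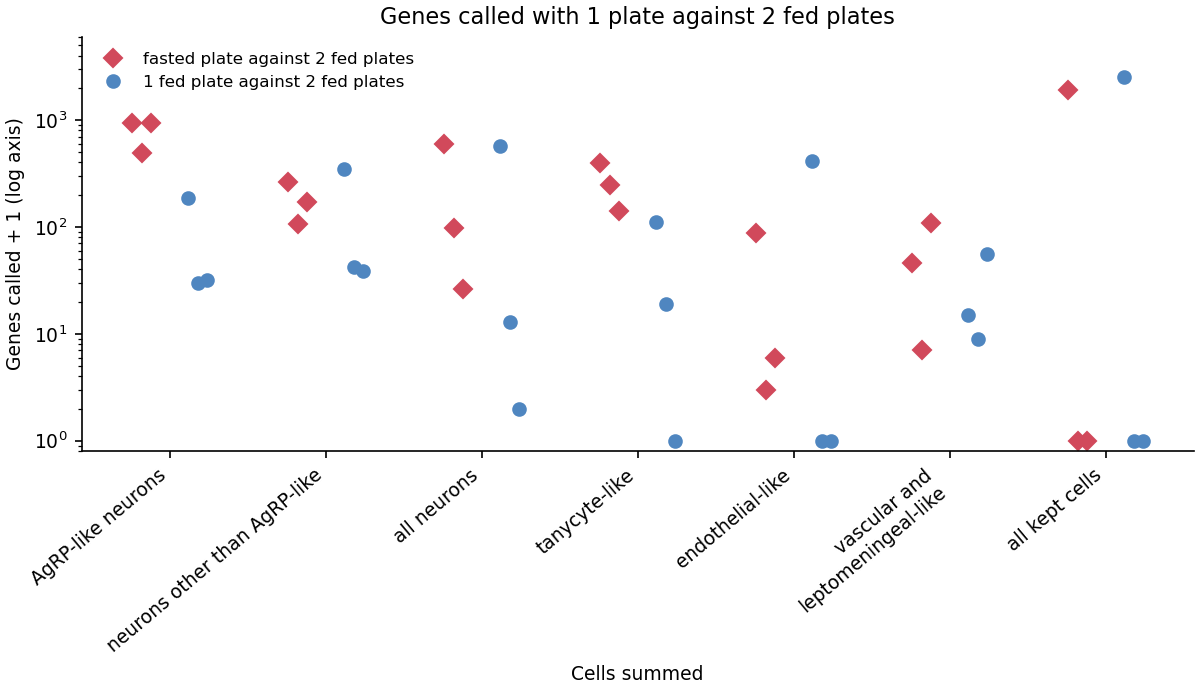
Number of genes past the edgeR threshold plus 1 (vertical axis, logarithmic) in each group of cells (horizontal axis), 1 point per fit, for the fasted plate against pairs of fed plates (diamonds) and each fed plate against the other fed plates (circles). In AgRP-like neurons the fasted plate gives 495 to 943 calls and the fed plates 29 to 187.

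In neurons other than AgRP-like, 14 of 12584 genes were higher and 4 lower on the fasted plate (25 cells, against 40, 52 and 75). Ngfr, the p75 neurotrophin receptor, fell from 50.4 ± 13.3 to 4.63 CPM (-3.43, SE 0.55, adjusted p = 0.0294, n = 3 fed plates by edgeR), Hspa1b from 145 ± 6.44 to 17.6 CPM (-3.03, SE 0.33) and Hspa1a from 209 ± 16.5 to 60.2 CPM (-1.80, SE 0.28). The phosphodiesterase Pde1c rose from 23.6 ± 5.42 to 83.4 CPM (1.83, SE 0.30), Usp51 from 26.8 to 91.7 CPM (1.76, SE 0.27) and Fam107a from 24.6 to 78.7 CPM (1.68, SE 0.28). The other rises named were of Rpl23a (1.87), the small gene Gm22710 (1.68) and the pseudogenes or predicted genes Gm6290 (2.80), Gm2033 (2.23), Gm9403 (1.96), Gm5963 (1.89) and Gm6368 (1.70), and Gm8055 fell (-1.60). Pseudogenes made up 9 of the 18 calls and are uncertain. Lepr (0.62, adjusted p = 0.696), Agrp (0.78, 0.441), Npy (0.63, 0.566), Pomc (-0.25, 0.845), Cartpt (-1.04, 0.705), Socs3 (-1.20, 0.801) and Gm2546 (-1.45, 0.0773) did not pass.

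Among the lists in these neurons, heat shock genes had 2 of 10 lower, Hspa1b and Hspa1a (1 higher and 4 lower adjusted over the list alone, median -0.69, camera adjusted p = 6.8e-07, adjusted p = 0.534 with an estimated correlation). No member of the other called lists passed over all genes. Glucocorticoid response genes had a median of 0.85, with 5 of 10 higher adjusted over the list alone and Errfi1 at 1.40 (adjusted p = 0.174). The camera adjusted p was 0.0005, and adjusted p = 0.534 with an estimated correlation. Medians were -0.43 for glycolysis (camera adjusted p = 0.0026), -0.32 for autophagy (0.0211), 0.42 for glutamate receptors (0.0052), -0.32 for oxidative phosphorylation (0.00078), 0.48 for the circadian clock (0.0237) and 0.64 for the AgRP peptides (0.0237), each at adjusted p = 0.596 with an estimated correlation. Adjusted over the list alone, 2 of 16 clock genes were higher, and none in the other lists of that group. Synaptic vesicle release had a median of -0.36 (0.0054, adjusted p = 0.534 with an estimated correlation) and none of 17 adjusted over the list alone, and ribosomal proteins 0.15, with 3 of 36 higher adjusted over the list alone (0.0237, adjusted p = 0.684 with an estimated correlation). The count of calls was 264, 105 and 170 without fed plates 1, 2 and 3, with all 18 genes called each time, while fed plates 1, 2 and 3 against the other fed plates gave 347, 41 and 38. Without Scrublet doublets the cells were clustered again, which took these neurons from 52 to 71 on fed plate 2. There 6 genes were called, all among the 18, and all 18 kept their direction, with a median fold 1.002 times as large.

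All neurons together gave 31 higher and 8 lower genes of 15067, in sums in which AgRP-like cells were 82 of 122, 59 of 111, 27 of 102 and 23 of 48 cells. Vgf rose from 226 ± 42.4 to 984 CPM (2.12, SE 0.23, adjusted p = 0.0127), Nptx2 from 18.8 ± 1.02 to 79.8 CPM (2.08, SE 0.21), Cd24a from 14.7 to 68.2 CPM (2.21, SE 0.25) and Cdkn1a by 3.23 (SE 0.49) from 2.29 CPM. Hspa1b fell from 176 ± 12.3 to 13.0 CPM (-3.75, SE 0.27), Sncg from 35.7 to 3.35 CPM (-3.39, SE 0.42), Hspa1a (-1.59), Tppp3 (-1.54), Gm8055 (-1.70) and Gm14539 (-2.79) fell, and Uty had 1 count on the fasted plate, a fed over fasted ratio of 80.6 (14.3 to 3194). Chga (1.60), Rps29 (1.42), Rpl23a (1.76), Gm6290 (2.80), Rpl10-ps2 (2.34), Gm9403 (2.31), Gm2033 (2.26), Gm6368 (2.05) and Gm5963 (1.89) rose. Agrp (1.16, adjusted p = 0.319), Npy (0.72, 0.569), Lepr (1.87, 0.208), Pomc (-0.31, 0.575), Cartpt (-0.91, 0.577) and Socs3 (-0.87, 0.519) did not pass. The lists called by camera numbered 11, with adjusted p from 0.415 to 0.687 with an estimated correlation. Medians were 0.91 for the AgRP peptides (1 of 6 higher, 5 adjusted over the list alone), -0.61 for heat shock (2 of 10 lower, 1 higher and 5 lower adjusted over the list alone), 0.40 for glucocorticoid response (1 of 11 higher, 4 adjusted over the list alone) and 0.18 for neuropeptide processing (2 of 14 higher, also adjusted over the list alone). Ribosomal proteins had a median of 0.12 (1 of 37 higher, 5 adjusted over the list alone). With no member past the threshold over all genes, cholesterol synthesis had -0.56, the clock -0.37, glycolysis -0.37, synaptic vesicle release -0.32, oxidative phosphorylation -0.26 and ER stress 0.10. Adjusted over the list alone 4, 2 and 2 genes of the cholesterol, clock and glycolysis lists were lower, 1 of glycolysis and 2 of ER stress were higher, and none passed in the remaining lists. The calls became 594, 97 and 25 without fed plates 1, 2 and 3, and fed plate 1 alone against the other fed plates gave 568. Without fed plate 3, Uty (0.0607), Hspa1a (0.0580), Gm14539 (0.0607), Tppp3 (0.0840), Rps29 (0.0800) and Chga (0.0955) did not pass, nor did Gm5963 without fed plate 1 (0.0873) and Chga without fed plate 2 (0.0745).

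Tanycyte-like cells of the fasted plate (43 cells, against 51, 74 and 73) had 149 genes higher and 94 lower of 10459. Wfikkn2, a secreted inhibitor of growth factors, rose from 16.5 ± 2.20 to 263 CPM (3.96, SE 0.36, adjusted p = 5.9e-17, n = 3 fed plates by edgeR), and the lipid-sensing nuclear receptor Pparg from 4.43 ± 2.03 to 71.5 CPM (3.95, SE 0.73). The glutamate receptor gene Gria1 rose from 127 ± 43.4 to 717 CPM (2.46, SE 0.26), Etnppl by 3.15 (SE 0.43), and Fmo2 (3.05), Aox1 (2.92), Dscaml1 (2.45), Gm16083 (3.24), B230323A14Rik (2.99) and Gm46218 (2.61) also rose. The protease inhibitor A2m fell from 201 ± 26.4 to 25.5 CPM (-2.96, SE 0.43, adjusted p = 4.0e-07). Dio3os and the interferon gene Ifit1 had 0 counts on the fasted plate and were at least 4.49-fold and 4.17-fold lower. Hbegf and D430019H16Rik had 1 count there, with fed over fasted ratios of 13.9 (2.38 to 561) and 12.2 (2.08 to 494). The Y-linked genes Uty, Eif2s3y and Kdm5d, at 0 counts, were at least 9.23-fold, 7.21-fold and 4.43-fold lower, Ddx3y had 1 count (ratio 52.6, 9.32 to 2087), and the pseudogene Gm14539 was at least 3.72-fold lower. Agrp (0.84, adjusted p = 0.319), Npy (0.53, 0.311), Cartpt (-1.04, 0.125) and Socs3 (-0.46, 0.776) did not pass.

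The camera lists in tanycyte-like cells all had adjusted p = 0.520 with an estimated correlation. Of 13 immediate early genes 2 fell (5 adjusted over the list alone), Dusp1 (-2.10, SE 0.41) and Fosb (-1.27, SE 0.33), with a median of -0.80 and camera adjusted p = 3.8e-06. Of 15 genes of glycolysis and glucose transport 3 fell (6 adjusted over the list alone), Eno1 (-1.28), Ldha (-1.15) and Tpi1 (-1.10), with camera adjusted p = 8.7e-05. Fkbp5 (1.29, SE 0.36) was the 1 of 12 glucocorticoid response genes to rise (3 adjusted over the list alone, camera 0.0011), and Hspa1b (-1.52, SE 0.40) the 1 of 10 heat shock genes to fall (3 adjusted over the list alone, camera 0.0011). Prox1 (1.33) and Zfpm2 (0.88) rose among 68 transcription factors (4 adjusted over the list alone, camera 0.0418). Chgb (2.37, SE 0.34) and Vgf (1.72, SE 0.37) rose among 12 genes of neuropeptide processing (2 adjusted over the list alone, camera 0.0063), with Chga at 187 CPM at most on a fed plate and 1002 CPM on the fasted plate. Vgf was also the 1 riser of 6 AgRP peptides (2 adjusted over the list alone, camera 0.0016). No member passed, adjusted over the list alone or over all genes, among 14 genes of fatty acid oxidation (median -0.49, 0.0175) and 25 of oxidative phosphorylation (-0.39, 0.0011). Pars tuberalis-like cells aside, Npy was seen in 98.1, 97.3 and 94.4% of cells of the named classes outside neurons on the fed plates. On the fasted plate it was seen in 98.9%. Pars tuberalis-like cells of the fasted plate held Chga at 25907 CPM. Vgf stood on that plate at 122 CPM in tanycyte-like, 136 in astrocyte-like, 189 in endothelial-like and 181 CPM in VLMC-like cells. These rises were thus not particular to tanycyte-like cells, and RNA of other cells as their source was not tested.

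The count of calls in tanycyte-like cells was 396, 243 and 140 without fed plates 1, 2 and 3, while fed plates 1, 2 and 3 against the other fed plates gave 110, 18 and 0. Without fed plate 3 the calls of Eno1 (0.0709), Ldha (0.0534), Tpi1 (0.0900), Fosb (0.109), Hspa1b (0.0749), Prox1 (0.0687), Kdm5d (0.0784), Gm46218 (0.0543), Gm14539 (0.361), D430019H16Rik (0.127) and Zfpm2 (0.0797) were lost. Without fed plate 2 those of Fkbp5 (0.128), Zfpm2 (0.129), Hbegf (0.0669) and D430019H16Rik (0.0976) were lost, and without fed plate 1 those of Dio3os (0.0684), Hbegf (0.0512) and D430019H16Rik (0.0984). With Xist-only cells of fed plates 2 and 3 and the fasted plate 12 genes were called, against 396 in all cells of these plates. Of the 243, 213 were tested there, and 212 of the 213 had the same direction, with a median fold 0.901 times that in all cells. Since 36 of the 43 tanycyte-like cells of the fasted plate were Xist-only, the sums share cells and the shared direction is no independent evidence.

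Astrocyte-like cells could be compared on fed plates 2 and 3 (28 and 37 cells) and the fasted plate (44 cells), where 20 genes were higher and 12 lower of 5323. The homeobox factor Zfhx3 rose from 165 ± 24.1 to 631 CPM (1.92, SE 0.32, adjusted p = 5.7e-06, n = 2 fed plates by edgeR) and Mfsd2a, a lipid transporter, from 109 ± 43.2 to 347 CPM (1.71, SE 0.41). Chga rose from 96.5 ± 38.1 to 1061 CPM (3.41, SE 0.32), with Chgb (1.87) and Vgf (2.02), in a plate whose pars tuberalis-like cells held Chga at 25907 CPM. Cep162 (2.78), Dennd4c (2.21) and Gm36346 (2.25) rose, as did Gm22710 and 2900060B14Rik (2.21), whose counts were identical and which are uncertain. The small heat shock gene Hspb8 fell from 178 ± 42.5 to 26.4 CPM (-2.74, SE 0.61), Sulf2 from 261 to 56.6 CPM (-2.20, SE 0.49) and Id3 from 365 to 121 CPM (-1.59, SE 0.39). Stmn3 (-2.62), Ctnna3 (-2.53), Ccdc114 (-2.40), Slc38a1 (-1.77) and Tagln3 (-1.69) fell, and Padi2 had 3 counts on the fasted plate (ratio 10.2, 3.17 to 52.0). Npy (0.70, adjusted p = 0.131) and Cartpt (-1.12, 0.510) did not pass. Of the 32 calls 1 was kept by DESeq2's Wald test, 14 with no filter on low counts and 24 at a minimum of 2000 transcripts. In Xist-only cells 10 of the 30 tested were kept. The median folds in these settings, in order, were 0.997, 1.04, 0.990 and 0.907 times as large.

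In astrocyte-like cells 4 lists were called by camera, each at adjusted p = 0.979 with an estimated correlation. They were the AgRP peptides (1 of 4 higher, Vgf, and 3 adjusted over the list alone, camera 9.4e-05), glucocorticoid response (1 of 7 higher, Mertk at 1.17, and 3 adjusted over the list alone, camera 0.0012), neuropeptide processing (3 of 10 higher, Chga, Chgb and Vgf, also adjusted over the list alone, camera 0.00014) and neuropeptides (1 of 5 higher, Vgf, and 4 higher and 1 lower adjusted over the list alone, camera 0.00014). Cck, a marker of the pars tuberalis-like cluster, was at 2.84 (adjusted p = 0.124).

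Endothelial-like cells of the fasted plate (17 cells, against 69, 19 and 19) had 16 genes higher and 1 lower of 4994. The haemoglobin genes led, with Hbb-bt above its 3.04 ± 5.27 CPM on the fed plates (7.62, SE 0.61, adjusted p = 1.4e-31, n = 3 fed plates by edgeR), Hbb-bs from 35.0 to 4219 CPM (6.62), Hba-a2 (5.05) and Hba-a1 (4.95), which are markers of blood cells. Zbtb16 rose from 124 ± 35.3 to 567 CPM (2.20, SE 0.48), Sult1a1 from 36.6 to 320 CPM (2.82, SE 0.56) and Aldh1a1 from 59.3 to 247 CPM (2.35, SE 0.60). Chga (3.03), Chgb (2.32), Rpl23a (2.64) and the pseudogene Gm6368 (3.01) rose, Chga against 35214 CPM in pars tuberalis-like cells of fed plate 1. Ddx3y, on the Y chromosome, had 0 counts and was at least 5.86-fold lower. Slc38a5 (-2.61, adjusted p = 0.0538), Serpinh1 (-2.31, 0.0887), Npy (0.36, 0.949), Cartpt (-0.83, 0.913) and Socs3 (0.45, 0.950) did not pass, nor did Plod1 (0.109) and Sh3bp5 at 1 count each, the latter at a ratio of 28.9 (5.12 to 1146), or Pomc at 0 counts (0.813).

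Glucocorticoid response genes in endothelial-like cells had 2 of 12 higher, Sult1a1 and Zbtb16 (6 adjusted over the list alone, median 1.16, camera adjusted p = 4.9e-09, adjusted p = 0.404 with an estimated correlation). Neuropeptide processing had Chga and Chgb higher of 8 (3 higher and 1 lower adjusted over the list alone, camera 0.00058), and the AgRP peptides none of 4 (2 adjusted over the list alone, camera 0.0016), each at adjusted p = 0.404 with an estimated correlation. Immediate early genes (median 0.84, none of 11, camera 0.0048) and oxidative phosphorylation (-0.46, none of 23, camera 0.0288) had none adjusted over the list alone and adjusted p = 0.848 with an estimated correlation. Fed plate 1 against the other 3 plates gave 283 calls, more than the 17 of the fasted plate against the other 3. The 17 became 86, 2 and 5 without fed plates 1, 2 and 3, where fed plate 1 against the other fed plates gave 409. Hbb-bt and Hbb-bs passed in each of these. Without fed plate 2 Hba-a2 (0.357), Hba-a1 (0.0905), Chga (0.796), Gm6368 (0.195), Sult1a1 (0.785), Rpl23a (0.464), Aldh1a1 (0.936), Chgb (0.936), Ddx3y (0.425) and Zbtb16 (0.464) did not pass. Without fed plate 3 Hba-a2 (0.0901), Hba-a1 (0.195), Chga (0.203), Sult1a1 (0.0562), Rpl23a (0.0669), Chgb (0.359) and Zbtb16 (0.286) did not, and without fed plate 1 Aldh1a1 (0.146) did not.

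VLMC-like cells of the fasted plate (13 cells, against 27, 30 and 31) had 6 genes higher and 3 lower of 5294. The sodium-calcium exchanger Slc8a1 rose from 30.1 ± 2.99 to 475 CPM (3.92, SE 0.56, adjusted p = 1.3e-05, n = 3 fed plates by edgeR) and Angptl4, a lipase inhibitor, from 49.4 ± 28.7 to 377 CPM (2.95, SE 0.58). Itga5 (2.93), Dleu2 (2.78) and Klf4 (2.08) rose. Cdh11 fell from 220 ± 63.3 CPM to 0 counts, at least 4.47-fold lower, Fxyd5 had 1 count (ratio 25.7, 4.55 to 1019) and H1f0 3 counts (ratio 8.17, at least 2.75 by its counting interval). Lepr (0.26, adjusted p = 0.849), Npy (0.39, 0.718), Cartpt (-1.01, 0.550), Socs3 (-0.02, 0.995), Tmsb4x (-2.22, 0.0756) and Htra3 at 2 counts (0.0510, ratio 10.3, 2.81 to 86.1) did not pass. With DESeq2's size factors 55 genes were called, 27 higher and 28 lower. With TMM the median over all genes was -0.11. Xist-only and Y-only VLMC-like cells of fed plates 2 and 3 differed in 36 of 1622 genes. That fit had plate as block and another set of genes, so its count cannot be set against that of the fasted plate.

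Angptl4 was the 1 of 12 genes of fatty acid oxidation and ketogenesis to rise in VLMC-like cells, also adjusted over the list alone (camera 0.0238), and no member passed over all genes in the other called lists. Glucocorticoid response had 3 of 10 higher adjusted over the list alone (median 0.52, camera 0.0161), neuropeptide processing 4 higher and 1 lower of 10 (0.0161), neuropeptides 2 of 6 (0.0275) and the AgRP peptides 1 of 4 (0.0238). Each of these had adjusted p = 0.494 with an estimated correlation. Members of these lists with the largest rises were Cck (4.59, adjusted p = 0.0516) and Chga (4.07, 0.312), which mark the pars tuberalis-like cluster, then Chgb (2.38, 0.0872). Immediate early genes had 1 of 11 higher adjusted over the list alone (median 0.54, camera 0.0161, adjusted p = 0.611 with an estimated correlation). The calls became 45, 6 and 108 without fed plates 1, 2 and 3, while fed plates 1, 2 and 3 against the other fed plates gave 14, 8 and 55. Without fed plate 2 Itga5 (0.118), Dleu2 (0.0863), Klf4 (0.226), Cdh11 (0.0601) and H1f0 (0.118) did not pass.

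Summed over all kept cells, no gene of 18241 passed edgeR's test between the fasted plate and the fed plates. At an unadjusted p under 0.05 there were 1500 genes, and DESeq2's Wald test called 80. The smallest p-values among higher genes belonged to Gm6290 (2.89, adjusted p = 0.422), Pex5l from 63.3 ± 2.33 to 251 CPM (1.99), Plekhh1 (2.11), Anln (3.37, 0.446) and Bpifa1, which had 0 counts on the fed plates and 766 on the fasted plate, at least 240.1-fold higher, with 686 of them in pars tuberalis-like cells. Among lower genes they belonged to Sncg (-2.73, 0.476), Gm8055 (-1.68), Hspa1b (-2.96, 0.477), Kdm5d at 1 count (ratio 76.2, 13.5 to 3024) and Uty at 1 count (182, 32.6 to 7219). Agrp (0.88, 0.627), Npy (0.50, 0.802), Lepr (1.28, 0.578), Pomc (-0.56, 0.613), Cartpt (-1.13, 0.624) and Socs3 (-0.03, 0.991) did not pass. Camera called 8 lists, among them the interferon response, which was not called elsewhere (median -0.93, none of 13 over all genes or adjusted over the list alone, camera 0.0296, adjusted p = 0.920 with an estimated correlation), and the others had adjusted p from 0.704 to 0.810 with an estimated correlation. The mix of cells enters these sums too. Neurons were 48 of 270 kept cells on the fasted plate, against 122 of 356, 111 of 322 and 102 of 331 on the fed plates. Medians of the other called lists were 0.66 for the AgRP peptides, 0.81 for glucocorticoid response, 0.20 for neuropeptide processing, -0.58 for heat shock, -0.54 for glycolysis, -0.50 for synaptic vesicle release and -0.33 for oxidative phosphorylation. Adjusted over the list alone, 1, 2 and 1 genes of the first 3 of these were higher, 3 heat shock genes were lower and none passed in the other lists. Without fed plate 1 the count was 1919, and fed plate 1 against the other fed plates gave 2504 calls.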

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

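The tests of differences between folds, of sex and RNA spread in endothelial-like cells and of the source of Npy were chosen after the results they measure had been seen, and the other tests of this part before.

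The fold of the fasted plate over the fed plates was larger in AgRP-like neurons than in the remaining neurons for Nptx2 (a log2 difference of folds of 3.91), Vgf (3.85), Sv2b (2.76), Lxn (2.55), Lepr (1.82), Hspa5 (1.38), Pdia6 (1.22) and Scg2 (0.91), and lower for Dbp (-4.15), Per3 (-3.14), Gas2 (-2.94), Tef (-2.23) and Nr1d2 (-1.39). Of these, Sv2b was not called in AgRP-like neurons themselves, where its fold was 1.14. On the fasted plate Chga stood at 933 CPM in AgRP-like neurons and 1002 CPM in tanycyte-like cells. Its difference against tanycyte-like cells therefore cannot be told apart from RNA of other wells. Against tanycyte-like cells the fold in AgRP-like neurons was larger for Lxn (3.30), Vgf (2.23), Hspa5 (1.62) and Pdia6 (1.58), and lower for Gas2 (-3.07), Hspa1b (-2.79), Lmo3 (-2.55), Per3 (-2.53), Dbp (-2.46), Nr1d2 (-1.49), Chgb (-1.48), Chga (-1.45) and Tef (-1.26). Each passed a test of the difference itself in edgeR with plate as block, which called 140 of 13684 genes against the remaining neurons and 173 of 13021 against tanycyte-like cells. Of the 654 genes called in AgRP-like neurons, 87 also differed in the same direction from the remaining neurons, and 73 of the 645 tested from tanycyte-like cells.

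Lists differed between groups of cells too. Against the remaining neurons the median difference of folds was -1.52 for the circadian clock (adjusted p = 0.226 with an estimated correlation), 0.73 for ER stress, 0.56 for neuropeptides, 0.46 for neuropeptide processing, 0.29 for the AgRP fasting peptides and 0.22 for autophagy (each at adjusted p = 0.369 with an estimated correlation), and -0.68 for cholesterol synthesis (adjusted p = 0.615 with an estimated correlation). Against tanycyte-like cells it was -1.13 for the circadian clock and 1.00 for ER stress (adjusted p = 0.180 with an estimated correlation), 0.42 for glycolysis and 0.40 for the AgRP peptides (adjusted p = 0.455 with an estimated correlation), and 0.90 for immediate early genes (adjusted p = 0.661 with an estimated correlation). All of these passed camera with the preset correlation.

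The 654 genes called in AgRP-like neurons lie between plates that differ in sex, depth and feeding state. The tables argue against the sex of the cells as the main source, since Xist-only minus Y-only AgRP-like cells of fed plates 2 and 3 moved the called genes by 0.0707 of their fold (0.0255 to 0.109, 478 genes). Deeper minus shallower AgRP-like cells of fed plates 1, 2 and 3 moved the called genes by 0.0198 of their fold (-0.00132 to 0.0473, 554 genes). This argues against depth within the range of the fed plates. Kept cells of fed plates 1, 2 and 3 held at most 57856, 65240 and 81257 transcripts, while AgRP-like cells of the fasted plate had a median of 65352. The split covers little of the fasted depth and cannot decide for it. A shift of the whole plate stays open, since tanycyte-like cells moved the same genes by 0.419 of their fold (0.359 to 0.493, 503 genes), between the bounds of 0.25 and 0.5 set beforehand. The ratio was 0.350 (0.255 to 0.449) for the higher genes and 0.534 (0.409 to 0.679) for the lower genes, an interval that holds the upper bound. Fasting may act on both cell types as a plate shift would, and with 1 fasted plate feeding state and plate cannot be told apart.

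Endothelial-like cells of fed plate 1 held Lcn2, Ackr1, Lrg1, Ch25h, Cxcl1, Ptgs2 and Cfb at a sum of 240.1 per 10000 transcripts in 69 cells, against 1.37 and 1.76 on fed plates 2 and 3 and 7.24 on the fasted plate. By cluster, these 7 genes summed to 256.6 in the 55 cells of cluster 8 and 40.6 in the 14 cells of cluster 6 on fed plate 1. Because these genes were singled out for that plate, tests used 10 genes picked from every other one of its endothelial-like cells against the fasted plate alone, of which 3 are among the 7. The sex of the cells as the sole source is argued against, since Y-only endothelial-like cells of fed plates 2 and 3 held the 10 genes at 0.00299 of their level in the remaining Y-only ones of fed plate 1 (0.000709 to 0.00914, 6 cells and 4 counts). RNA spread evenly over the wells as the source of these levels is argued against too. Tanycyte-like cells of fed plate 1 stood at a median of 0.0209 of the remaining endothelial-like cells over the 10 genes (lowest to highest gene 0.00622 to 0.0449). Of these genes, Lcn2, Ackr1, Cfb and Gm20547 also led cluster 8, which was ranked against all other cells. Their low ratios could thus be foreseen, and the other picked genes were not among its leading genes. The test does not exclude a smaller spread of this RNA from endothelial-like cells. The 7 genes summed to 8.60 per 10000 in tanycyte-like and 6.68 in AgRP-like cells of fed plate 1, against the 1.37, 1.76 and 7.24 in endothelial-like cells of the other plates. No biological explanation was tested, since the design names no group that sets fed plate 1 apart.

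Npy appeared in wells that entered no comparison. The wells under 1000 transcripts held 2.18, 2.35 and 1.67 Npy transcripts per well on the fed plates and 1.18 on the fasted plate, and Npy was seen in 22 of 28, 42 of 55, 26 of 46 and 37 of 109 of them. Their median depths were 365.5, 372 and 572 transcripts on the fed plates and 25 on the fasted plate. As a share, Npy was at 5316, 5356 and 3003 CPM there and 8377 CPM on the fasted plate. In kept cells of the named classes outside neurons, pars tuberalis-like cells aside, RNA from AgRP-like neurons as the sole source of Npy is argued against. Their ratio of Npy to Agrp was at least 4.65 times that in AgRP-like neurons on each plate. The ratio was not computed for the wells under 1000 transcripts, so the source of their Npy stays open. On each plate the Npy share of these wells lay between that of those kept cells and that of AgRP-like neurons. Where the Npy outside AgRP-like neurons comes from was not tested further.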

How the results depend on the processing

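The fits on Xist-only cells and without Scrublet doublets were tests chosen after the data were seen. Over all alternatives, 349 of the values that answer a comparison kept their direction and side of the threshold or stayed within 1.5 times their count, and 88 did not. Among named genes 4685 did, 301 lost and 273 gained a call, and 20 changed sign. Of the shares of classes on each plate, those of endothelial-like cells on fed plate 1 became 8.43% at higher resolution, and without Scrublet doublets neurons on fed plate 2 became 40.5% and pars tuberalis-like cells on fed plate 3 became 0%. No cluster was named POMC-like (0% of each fed plate) at lower resolution, with all variable genes, at minima of 500 and 2000 transcripts or without Scrublet doublets. The other shares given stayed within their intervals. Where no reason is given, the cause was not tested.

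With the Wald test of DESeq2 the counts were 80 in all kept cells, 63 in all neurons, 188 in AgRP-like neurons, 20 in tanycyte-like, 1 in endothelial-like, 1 in astrocyte-like and 0 in VLMC-like cells (184 there at an unadjusted p under 0.05). With no filter on low counts they were 513 in all kept cells, 407 in all neurons, 181 in other neurons, 157 in tanycyte-like, 11 in endothelial-like, 16 in astrocyte-like and 29 in VLMC-like cells. With Xist-only cells, where fed plate 1 was left out as well, they were 191, 270, 56 in AgRP-like and 217 in other neurons, 12 in tanycyte-like, 61 in endothelial-like, 13 in astrocyte-like and 39 in VLMC-like cells. All cells without fed plate 1 gave 1919, 594, 932, 264, 396, 86 and 45 in the same order, astrocyte-like cells aside, for which fed plate 1 was never used. Thinning each cell to 1000 transcripts gave 18 genes in all kept cells, up from 0, and 4 in AgRP-like neurons, where 1416 genes were tested against 13075, and was run for these sums alone. Without a fed plate the counts ran from 0 to 1919 in all kept cells, 25 to 594 in all neurons, 495 to 943 in AgRP-like neurons, 105 to 264 in other neurons, 140 to 396 in tanycyte-like, 2 to 86 in endothelial-like and 6 to 108 in VLMC-like cells. Without Scrublet doublets, with the cells clustered again, they were 25 in all neurons, 6 in other neurons and 9 in endothelial-like cells, with the called genes at medians of 1.002, 1.002 and 0.983 times their fold. Other neurons on fed plate 2 went from 52 to 71 cells there, so doublets and clustering changed together. Endothelial-like cells gave 28 at higher resolution, 7 at lower resolution and 6 at a minimum of 500 transcripts. VLMC-like cells gave 55 with DESeq2's size factors, 56 with all variable genes and at higher or lower resolution, and 68 and 55 at minima of 2000 and 500 transcripts. Those minima kept 1213 and 1329 cells. After thinning, 139 of the genes called in AgRP-like neurons were still tested. Of these, 131 kept their direction, and the median fold was 1.06 times as large.

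An estimated correlation left 0 lists called in each of the 8 comparisons, against 10 in AgRP-like neurons, 8, 11 and 10 in all kept cells, all neurons and other neurons, and 9, 5, 4 and 6 in tanycyte-like, endothelial-like, astrocyte-like and VLMC-like cells. That setting tests on 2 residual degrees of freedom at most, so the loss does not show that correlation between genes removed the calls. Without a fed plate, endothelial-like cells had 3 to 6 lists called. Without a plate, transcription factors and receptors higher in a class ran from 6 to 15 in oligodendrocyte-like (lowest without the fasted plate, which holds most of the cells) and 9 to 20 in pericyte-like cells. Without thinning, Lepr was seen in 54.5% of AgRP-like and 46.4% of other neurons, 45.5% of VLMC-like, 18.5% of endothelial-like, 4.15% of tanycyte-like and 3.57% of astrocyte-like cells, since depth limits detection.

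Signs changed for genes not past the threshold. Against the remaining neurons Lepr in AgRP-like neurons ran from -0.20 (without the fasted plate) to 0.75, and in pericyte-like cells against the remaining cells from -1.17 to 0.46 (without fed plate 3), with 0.15 without the plate block. In all kept cells thinning gave Pomc 0.13 and Lepr -0.66, and Socs3 ran from -0.31 to 0.37 (highest without fed plate 1) and stood at 0.28 in Xist-only cells. In AgRP-like neurons Pomc ran from -0.0164 (without fed plate 2) to 0.19 and Errfi1 stood at -0.97 after thinning. In other neurons Pomc ran from -0.51 to 0.0446 (without fed plate 1), and Xist-only cells gave Pomc 0.37, Lepr -0.14 and Errfi1 -0.0230, with Sst at -0.79 with all variable genes. Socs3 in tanycyte-like cells ran from -0.80 to 0.12 (without fed plate 1) and stood at 0.32 in Xist-only cells. In VLMC-like cells it ran from -0.33 to 0.82 (without fed plate 1) and stood at 0.0182 with DESeq2's size factors and 1.04 in Xist-only cells, where Lepr stood at -0.0390. Leaving out a fed plate was not run for astrocyte-like cells, since 1 plate against 1 leaves no residual degrees of freedom. No paired analysis was possible because nothing pairs the fasted plate with a fed plate.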

Other observations

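No tests were added for this part, and its clusters were singled out after their values were seen. Among neurons outside the AgRP clusters, the Lepr level summed over plates was highest in the unnamed cluster N0, at 155 CPM (122.6 ± 52.6 CPM over the 3 fed plates). The cluster was led by Cox6a2, Cntnap5a, Nkx2-4 and St18, and Lepr was seen in 78.1% of its 32 cells, or 18.8% after thinning to 1000 transcripts. It held 6, 7 and 15 cells of the fed plates and 4 of the fasted plate. The next cluster, N2, stood at 94.5 CPM (83.0 ± 77.2 CPM over 2 fed plates). The ranking is not separated from the mix of plates in each cluster. Among VLMC-like cells, cluster 13, led by Igfbp2, Ptgds and Bmp6, stood at 297 CPM over 38 cells (300 ± 167 CPM over the 3 fed plates) and cluster 9 at 136 CPM over 54 cells (125 ± 47.0), a difference that was not tested.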
